A study of Nothobranchius furzeri with 6 samples.

How the data were processed

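Small RNA was sequenced from brains of the turquoise killifish Nothobranchius furzeri, a short-lived annual fish used in ageing research. The 6 libraries came from males of the wild-derived laboratory strain MZM-04/10p, all 39 weeks old, and all fall into 1 group. Per the labels, the molecule was total RNA, and per the labels' protocols libraries were made with Illumina's TruSeq small RNA kit. That kit ligates adaptors directly to the RNA ends. Ligation efficiency depends on sequence, so a ratio between the counts of different miRNAs mixes abundance with this bias. The spread of 1 row between libraries is less exposed to it, but a shift between family members counted in the same row could still move it.

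The authors deposited 1 table of raw counts, with whole numbers for 324 features in 1 column per library. Of these features, 235 carry a miRNA family name and 89 are called predicted features. The submitters' processing notes list bcl2fastq 1.8.4, Trimmomatic 0.36, BWA 0.7.12-r1039 and SAMtools 1.3.1-9. What each was used for, the genome build, the miRNA annotation, the mismatches allowed and the treatment of reads that match several places are not given in the sources used here. The deposited counts are not split into 5p and 3p arms or into family members. Names are those of families across animals, plants and viruses, so lin-4 (a name that also covers miR-125) and mir-8 (a name that also covers miR-141, miR-200 and miR-429) and mir-10 (a name that can also cover miR-99 and miR-100) stand where a vertebrate catalogue would use other names. Near-identical families can share reads, and their split is uncertain. No coordinates are given because the table of counts carries none and no genome with miRNA annotation was used here.

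Replicate numbers 1 to 6 were given in accession order and only name the libraries. The labels carry a separate code per library but do not state that each came from a separate animal, so p-values measure the spread between these 6 samples. Total counts ranged from 11924483 to 16597229. A count of 3, taken as the detection floor, corresponded to 0.173 to 0.256 CPM across libraries, where CPM is the count per library total after scaling. Exact (Clopper-Pearson) 95% binomial intervals are given for values of single libraries. These intervals and the floor cover counting error only, since reads without molecular identifiers are not independent molecules.

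Counts were scaled with edgeR's TMM factors (0.958 to 1.05) and are given as CPM, mean ± SD over 6 libraries. Log2 values are log2(CPM + 1). Shares of lists are percentages of all counts in a library, without TMM. Features with a mean of at least 10 counts, 214 in all, entered the test for variation between libraries. An intercept-only negative binomial model was fitted with edgeR at the trended dispersion, and the goodness-of-fit chi-square was adjusted by Benjamini-Hochberg over the 214 features with a threshold of 0.05. The median biological coefficient of variation on this trend was 0.371. It was 0.274 for edgeR's tagwise dispersions, which are values per feature shrunk toward the trend. The test is therefore conservative for typical features. Tested on counts simulated for these 214 features in 20 runs, it found 79% of the features given an extra log2 SD of 2, 18.5% of those given an extra log2 SD of 1, and made no false calls. Features given no extra variation were drawn at the trended dispersion that the test assumes. The absence of false calls therefore does not extend to features whose dispersion lies off the trend.

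Before the data were examined, 17 lists of miRNA families were fixed: markers of neurons, neural progenitors, oligodendrocytes, red blood cells, white blood cells with microglia, vessel wall, muscle, epithelium and skin, sensory organs with retina and pineal, endocrine tissue with pituitary, liver and early embryo, families linked to Hox genes, let-7, miR-29, the miR-17-92 cluster with its paralogues, and other families studied in ageing vertebrate brain. Family numbers were matched to rows by name. The list families miR-212, miR-206, miR-141, miR-429, miR-211, miR-98, miR-18, miR-20, miR-93, miR-106, miR-363 and miR-125 matched no row by their own name and are not analysed here under it. Summed counts of the neuronal list were compared with those of each of the 16 other lists by an exact two-sided sign-flip permutation test on the within-library log2 ratio, which cannot give a p under 0.03125 with 6 libraries. For 10 of 12 fixed pairs of families or lists, Pearson's r and Spearman's rho of log2 CPM were tested over all 720 pairings. The other pairs could not be computed because mir-20 and mir-212 have no row of their own name. Whether reads of families without such a row were counted under another family name is not known. On simulated data with no effect, the sign-flip test called 3.25% and the correlation test 4.5% of 400 data sets.

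Genes to be named were fixed by rule beforehand: the 15 features with the highest mean CPM, list members with a mean of at least 100 CPM (at most 4 per list), and up to 10 features with the largest log2 SD among those past the variability test. Families named outside this rule, among them mir-200, mir-124, mir-499, mir-203, mir-194, mir-135, mir-458, mir-BART15, mir-228 and the members of genomic clusters, were singled out after their values were seen or belong to a fixed pair. Arm preference had been planned and could not be tested, since the counts carry no arm names. Alternatives were other scalings (DESeq2 size factors, plain CPM), other count minimums, DESeq2 dispersion outliers, a Poisson index of dispersion, other ways to sum lists, and leaving out each library. Added after the data were seen were a dispersion trend fitted without the called features, lists with mir-8 and lin-4 matched, and tests of neighbouring ranks. Software was Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3, matplotlib 3.10.9, R 4.3.3, edgeR 4.0.16 and DESeq2 1.42.0.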

Results

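The miRNA content of the brain was measured in 6 small RNA libraries from male killifish aged 39 weeks. Because all libraries belong to 1 group, the design gives the level of each miRNA family and its spread between libraries, comparisons between families within libraries, and no contrast of age, sex or strain. Total counts were 11970136, 14531614, 16597229, 11924483, 12589535 and 12776508 in libraries 1 to 6. Of 324 features listed, 191 had at least 10 counts in each library, 163 of them named families and 28 predicted features. Predicted features together took 0.338% ± 0.0463 (SD, n = 6) of all counts. Another 38 features had 0 counts in each library, which allows up to 0.256 CPM per feature in the shallowest library; this bounds the rows and not the families, since the mir-200 row is at 0 while mir-8, a name that also covers miR-200, is not. Across the 214 features with a mean of at least 10 counts, log2 CPM correlated between libraries with r of 0.979 to 0.993. These are correlations across features, which are not independent replicates. All library pairs differed by more than counting noise, with a chi-square per degree of freedom of at least 365, so none was treated as 1 library deposited again; this does not tell whether any libraries came from the same animal.

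The first question was which miRNA families make up the small RNA of the brain at 39 weeks. A few families took most of the counts: the 10 most abundant features held 78.9% ± 0.779 (SD, n = 6). The mir-181 family, known from brain and lymphoid tissue, was the most abundant at 291914 ± 10918 CPM, or 29.2% ± 1.73 of all counts. It was followed by mir-26 at 124024 ± 15278 CPM and let-7, the conserved family that promotes differentiation, at 87977 ± 3406 CPM. The neuronal family mir-128 reached 65311 ± 14644 CPM, lin-4 reached 53241 ± 3936 CPM and mir-9, a family of neural progenitors and neurons, reached 52186 ± 3512 CPM (SD, n = 6 for each). Next came mir-10 at 35722 ± 7039, mir-22 at 28269 ± 1710, mir-221 at 27219 ± 9073 and mir-27 at 23879 ± 3476 CPM. The remaining members of the top 15 were the activity-regulated neuronal family mir-132 at 19494 ± 2960, mir-724 at 18116 ± 2197, the oligodendrocyte family mir-338 at 17550 ± 1917, mir-92 at 17034 ± 2224 and mir-21 at 12133 ± 1184 CPM.

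**Figure D1:**
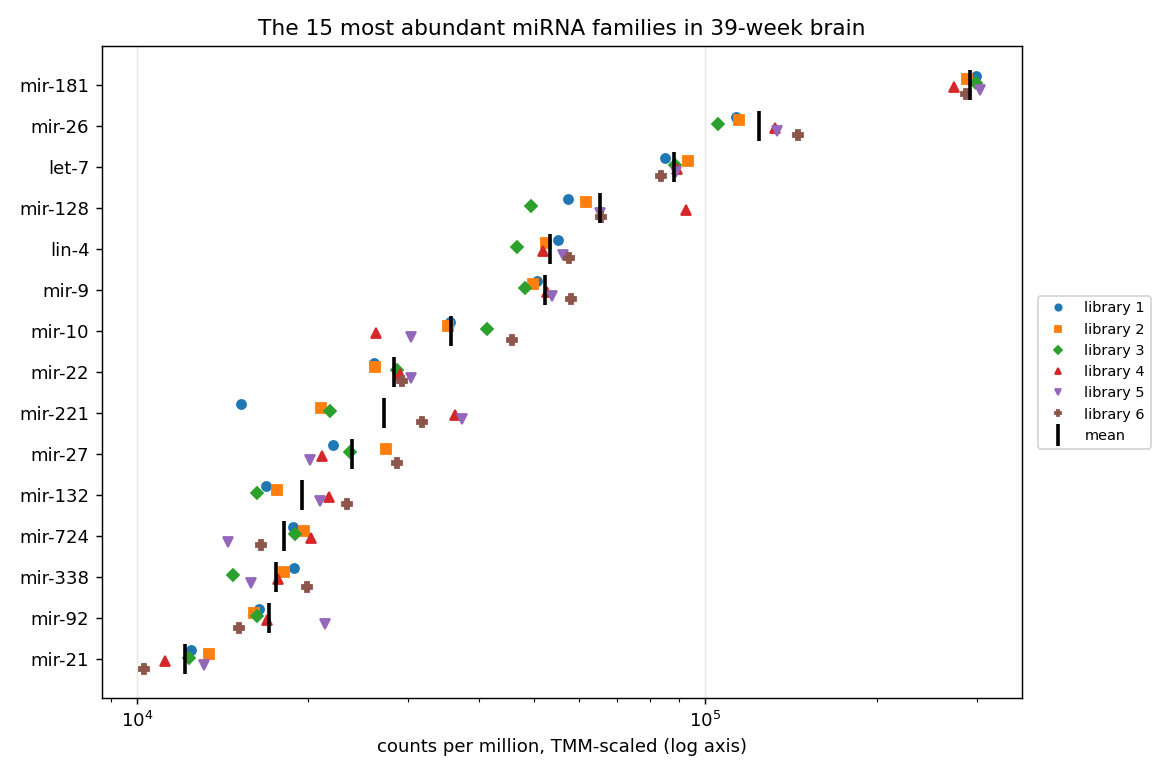
CPM (TMM-scaled, log axis) of the 15 most abundant families; each symbol is 1 of 6 libraries and the bar is their mean. The mir-181 points lie between 274077 and 304082 CPM, apart from every other family, whereas mir-221 spreads from 15261 to 37260 CPM.

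Neighbouring ranks were not all separable. In each of the 6 libraries mir-181 exceeded mir-26 (log2 ratio 1.24 ± 0.20), mir-26 exceeded let-7 (0.49 ± 0.20), mir-128 exceeded lin-4 (0.27 ± 0.29), mir-9 exceeded mir-10 (0.57 ± 0.29) and mir-92 exceeded mir-21 (0.49 ± 0.16). Each of these had p = 0.03125 in the exact two-sided sign-flip permutation test, the smallest that 6 libraries allow, and an adjusted p of 0.0875 over the 14 steps of the ranking. No step of the ranking therefore passed after adjustment. With this smallest p, a lone step cannot pass over 14 steps, however large its ratio. The adjusted p therefore cannot tell a large step, such as mir-181 over mir-26, from a small one. The levels of lin-4 and mir-9 differed by a log2 ratio of only 0.03 ± 0.07, with lin-4 higher in 3 of 6 libraries. These steps were tested after the ranking was seen, and ligation bias enters every ratio between families.

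The second question was how much of the library came from families known to mark particular cell types. The neuronal list held 11.3% ± 1.55 of all counts (SD, n = 6), with 8 of its 9 families present as 9 rows. Its counts were mostly mir-128, which made up 57.5% ± 3.56 of the list, and mir-132, which made up 17.4% ± 1.70. The family mir-153 stood at 8708 ± 2179 CPM and mir-132b at 5453 ± 650 CPM. Classical neuronal mir-124 made up only 3.74% ± 1.06 of the list. The progenitor and neuron list, which is mir-9 alone, held 5.21% ± 0.190. Oligodendrocyte families held 1.87% ± 0.174, nearly all of it mir-338, with mir-219 at 1145 ± 77.2 CPM.

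Families of other tissues and of blood were present at lower shares. Vessel wall families held 0.885% ± 0.148, led by smooth-muscle mir-143 at 4743 ± 731 CPM and endothelial mir-126 at 3816 ± 691 CPM, with mir-145 at 276.6 ± 89.5 CPM. The list of sensory organs, retina and pineal held 1.08% ± 0.0941, led by mir-204 at 8136 ± 396 CPM. The sensory cluster families mir-182 and mir-183 stood at 2229 ± 296 and 361.2 ± 66.7 CPM. Muscle families held 0.111% ± 0.0222, of which mir-133 at 1076 ± 189 CPM made up 97.6% ± 0.811. The other muscle rows were far lower, with mir-1 at 22.9 ± 7.76 CPM and mir-499 at 3.01 ± 2.18 CPM. White blood cell and microglial families held 0.0494% ± 0.00640, with mir-146 at 252.6 ± 96.6 CPM and mir-142 at 174.0 ± 41.6 CPM. The red blood cell families held 0.0473% ± 0.0166, with mir-451 at 346.6 ± 111 CPM and mir-144 at 124.1 ± 56.0 CPM. Epithelial and skin families held 0.0239% ± 0.0181, and mir-205 alone stood at 197.4 ± 150 CPM. This share leaves out mir-8, the name that also covers miR-141, miR-200 and miR-429, and with mir-8 (451.1 ± 204 CPM) added the list held 0.0685% ± 0.0152. Endocrine and pituitary families held 0.115% ± 0.0664, with mir-375 at 598.4 ± 677 CPM and mir-7 at 562.6 ± 248 CPM. The liver list held 0.00106% ± 0.0000794 and early-embryonic mir-430 held 0.000857% ± 0.000612.

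**Figure D2:**
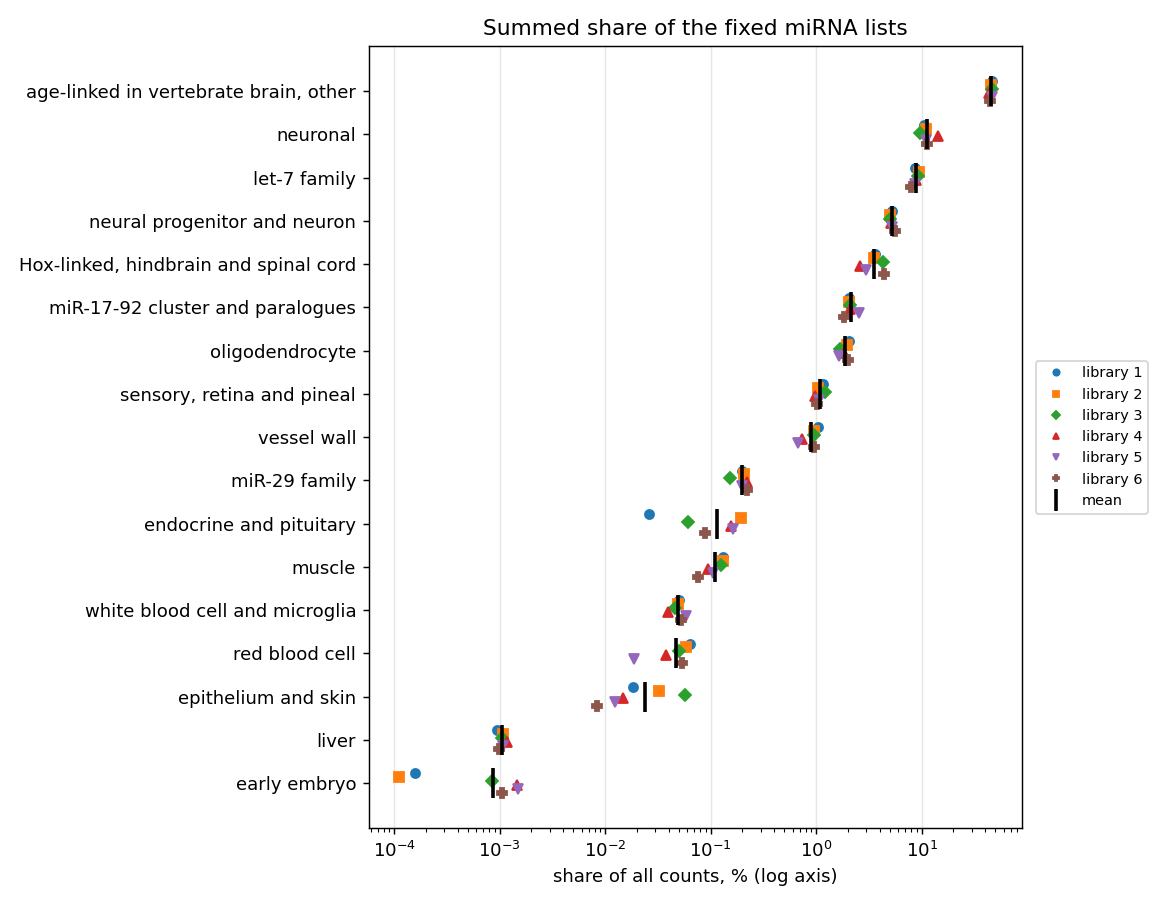
Share of all counts (%, log axis) of the 17 lists fixed beforehand; each symbol is 1 library and the bar is the mean of 6. The neuronal list lies near 11.3%, while the endocrine, red blood cell, epithelial (without mir-8) and early embryo lists spread widest between libraries.

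Lists linked to ageing and growth made up much of the rest. Other families studied in ageing vertebrate brain held 45.5% ± 1.12 of all counts, of which mir-181 made up 64.2% ± 2.46, mir-26 27.2% ± 2.84, mir-21 2.67% ± 0.279 and mir-30 2.43% ± 0.258. This share leaves out lin-4, the name that also covers miR-125, and with lin-4 added the list held 50.8% ± 1.23. The let-7 family held 8.80% ± 0.504. The miR-17-92 cluster, a growth-promoting cluster, held 2.12% ± 0.238 with its paralogues, and 80.1% ± 1.27 of that was mir-92. Within this list mir-25 stood at 2029 ± 368, mir-19 at 1205 ± 66.1 and mir-17 at 977.2 ± 80.9 CPM. The miR-29 family stood at 1998 ± 293 CPM, or 0.199% ± 0.0242 of counts. Hox-linked families held 3.58% ± 0.718, nearly all of it mir-10, a name that can also cover miR-99 and miR-100. How much of this share is miR-10 itself is therefore not known. The other row, mir-196, made up 0.00849% ± 0.00363 of the list. With a single age, none of these levels can be read as a change with age.

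Of the 16 other lists, 15 lay below the neuronal list and 1, the list of other ageing-linked families, lay above it, each in 6 of 6 libraries. The exact two-sided sign-flip permutation test gave p = 0.03125 for every list, and the Benjamini-Hochberg adjusted p was also 0.03125. The adjusted p stayed at this smallest possible value only because every list reached it. The log2 ratio of the neuronal list to the others was 0.35 ± 0.23 for let-7, 1.10 ± 0.18 for mir-9, 2.59 ± 0.21 for oligodendrocyte families, 3.68 ± 0.39 for vessel wall, 7.83 ± 0.33 for white blood cells and microglia, 7.99 ± 0.73 for red blood cells and 13.37 ± 0.14 for liver (mean ± SD, n = 6). Against the other ageing-linked families it was -2.03 ± 0.22. The order against let-7 and mir-9 rested on mir-128: without it the log2 ratio was -0.89 against let-7 and -0.14 against mir-9. With member medians in place of sums, the ratio also reversed against let-7 (-4.21), mir-9 (-3.45), Hox-linked (-1.89) and oligodendrocyte (-0.97) families, and the vessel wall list no longer passed (0.34, adjusted p = 0.1875 in the same exact test). The reversals set the middle of 9 neuronal rows against lists of 1 row (let-7, mir-9) or 2 rows (Hox-linked, oligodendrocyte). List length therefore enters them. It enters the sums as well, since a longer list adds up more rows. The neuronal list and the list above it had 9 rows each, and the lists below it had 1 to 6.

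The third question was which families differed between libraries of the same age, sex and strain. Most did not differ much: the median log2 SD of the 214 tested features was 0.27, and 182 of them had a log2 SD under 0.5. The 1 added to CPM compresses this SD for rows near 1 CPM. Among the 182, mir-770 ranged 6.01-fold with a log2 SD of 0.497, and mir-408 ranged 6.39-fold with 0.483. By edgeR's goodness-of-fit test, 8 features varied more than features of like abundance at an adjusted p under 0.05, and 18 had an unadjusted p under 0.05. The count was 3 as DESeq2 dispersion outliers, 22 with the trend fitted without the called features and 177 by a Poisson index of dispersion. Endocrine mir-375 varied most, with a log2 SD of 3.68 and an adjusted p of 9.6e-28. It stood at 1574, 863.2 and 1104 CPM in libraries 2, 4 and 5, and at 7.56, 37.2 and 5.23 CPM in libraries 1, 3 and 6. The exact 95% interval was 1553 to 1594 CPM in library 2 and 4.03 to 6.68 CPM in library 6, a 300.99-fold range between these libraries. The other endocrine family, mir-7, ranged from 244.3 CPM in library 1 to 921 CPM in library 6.

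The other called families were low in abundance. The family mir-995 (adjusted p = 8.4e-15) stood at 25.8, 25.9 and 30.2 CPM in libraries 2, 3 and 4 and at 0.569, 0.653 and 0.490 CPM in libraries 1, 5 and 6, with 6 to 8 counts in each of the latter. The exact 95% interval of library 4 was 27.1 to 33.5 CPM and that of library 6 was 0.180 to 1.07 CPM. The family mir-192 (adjusted p = 4.6e-04), known from gut, liver and kidney, ranged from 267.1 CPM in library 1, with an interval of 258 to 276 CPM, to 16.9 CPM in library 6, with an interval of 14.7 to 19.4 CPM. Early-embryonic mir-430 (adjusted p = 4.6e-04) was at 1.54 and 1.09 CPM in libraries 1 and 2 and at 8.11 to 15.4 CPM in the other 4. The family mir-883 (adjusted p = 3.4e-04) ranged from 0.408 CPM in library 6 to 8.97 CPM in library 3. Among predicted features, pred_185 was at 1.47 CPM in library 6 and at 36.1 to 114.5 CPM elsewhere (adjusted p = 5.6e-05). The feature pred_484 was highest in libraries 1 and 6, at 178.0 and 135.9 CPM, against 25.4 to 42.8 CPM in the others (adjusted p = 0.0057). The feature pred_347 ranged from 0.171 CPM, which is 2 counts, to 3.92 CPM (adjusted p = 0.0033).

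**Figure D3:**
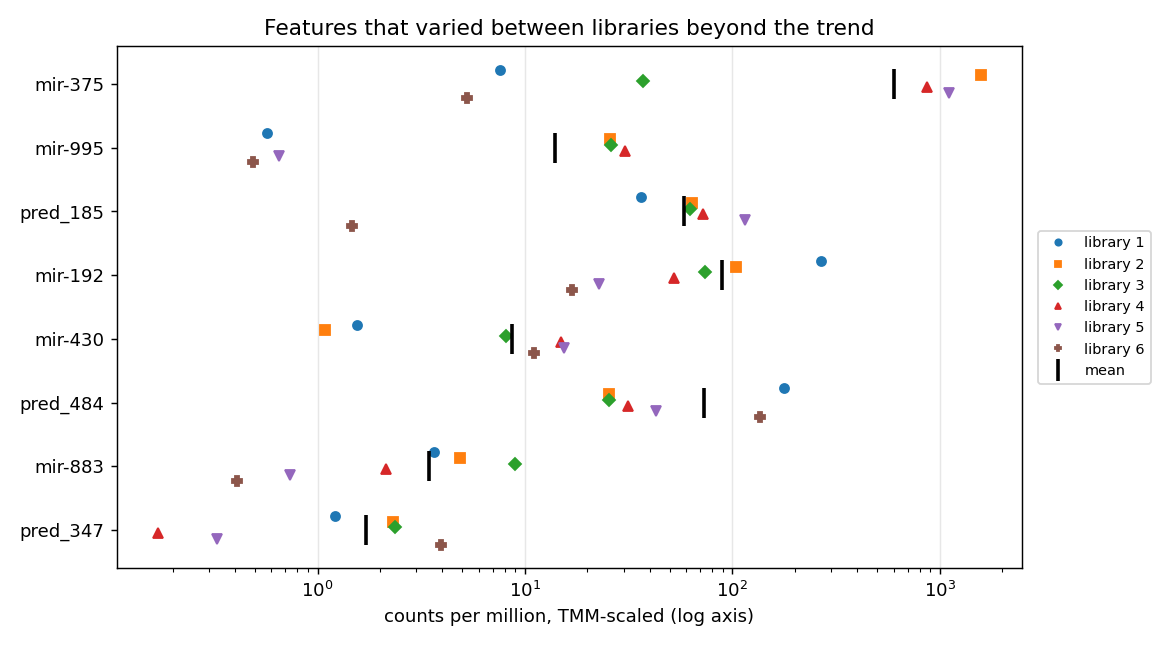
CPM (TMM-scaled, log axis) of the 8 features past the variability test; each symbol is 1 library and the bar is the mean of 6. For mir-375, libraries 2, 4 and 5 lie between 863.2 and 1574 CPM and libraries 1, 3 and 6 at or below 37.2 CPM.

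Calls differed in how far they rested on 1 library. The calls of mir-375, mir-995 and mir-883 remained past the threshold when any single library was left out, by edgeR's test. By the same test, mir-192 was lost without library 1 (adjusted p = 0.152), mir-430 without library 2 (0.134), pred_347 without library 4 (0.201), pred_185 without library 6 (0.9998), and pred_484 without library 1 (0.0943) or library 2 (0.0766). Among the lists, 1 endocrine member (mir-375) and the only early embryo member (mir-430) passed over all features tested. Adjusted over the list alone, 1 muscle member (mir-499) and 1 epithelial member (mir-205) passed as well, and no member of the neuronal, oligodendrocyte, blood or vessel wall lists passed either way. Fitting the trend without the called features drops the most variable features of the same data, which favours further calls. False calls were not simulated for that setting. With that trend, red blood cell mir-144 (adjusted p = 0.0181), mir-7 (0.0393), mir-205 (4.7e-05) and mir-499 (0.0092) also passed edgeR's test over all features. With the main trend, mir-205 passed the same test without library 1 (0.0410). Left-out libraries also moved these families the other way: the adjusted p of mir-205 was 0.9999 without library 3 and 0.109 to 0.250 without library 2, 4, 5 or 6. For mir-144, mir-7 and mir-499 it lay between 0.157 and 0.9999 without any single library, and was 0.990 for mir-499 without library 2.

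**Figure D4:**
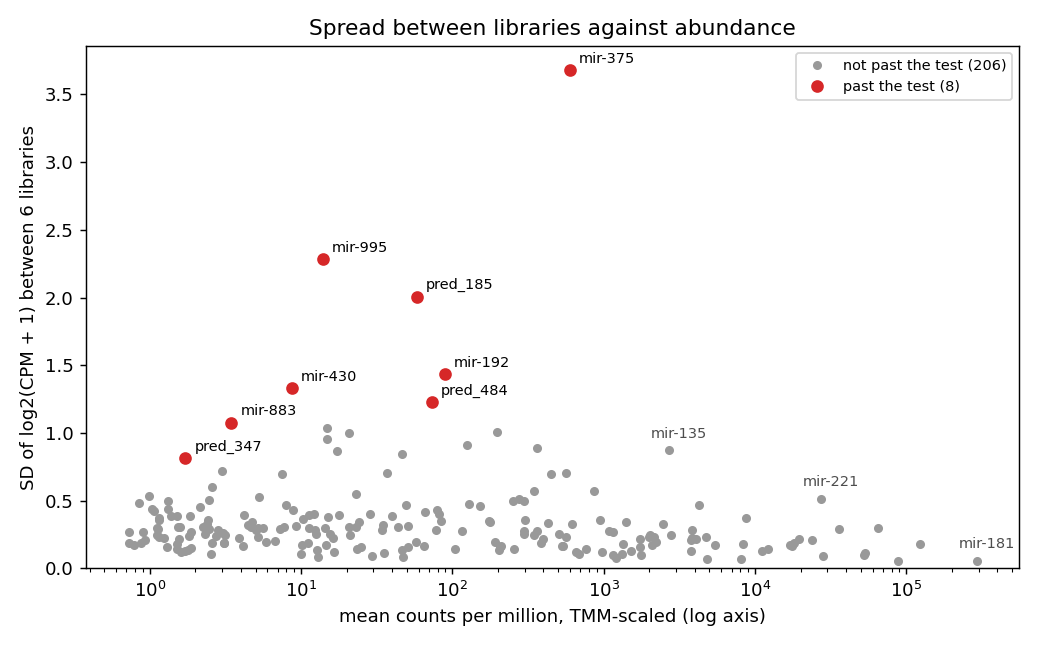
SD of log2(CPM + 1) between 6 libraries against mean CPM (log axis) for 214 tested features; red points are the 8 past the variability test and grey points are the other 206. The red mir-375 point lies at an SD of 3.68, while mir-181 lies at 0.05.

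The last question was whether families that share a cell type or a transcript moved together over the 6 libraries. Of the 10 pairs that could be computed, none passed after Benjamini-Hochberg adjustment, and 2 had an unadjusted exact permutation p under 0.05 for Pearson's r. The sensory cluster families mir-182 and mir-183 had r = 0.87 (exact permutation p = 0.0125, adjusted p = 0.125) and rho = 0.89 (exact p = 0.0333, adjusted p = 0.333), with r = 0.78 after the 2 libraries farthest from the median were left out. The red blood cell families mir-144 and mir-451 had r = 0.90 (exact permutation p = 0.0486, adjusted p = 0.243) and rho = 0.54 (exact p = 0.297, adjusted p = 0.699), and r fell to 0.52 without the 2 farthest libraries. Both red blood cell families were lowest in library 5, at 32.2 CPM for mir-144 and 159.2 CPM for mir-451. The oligodendrocyte families mir-219 and mir-338 had r = -0.25 (exact permutation p = 0.651, adjusted p = 0.730), rho = -0.37 (exact p = 0.497, adjusted p = 0.705) and r = -0.56 without the 2 farthest libraries. The oligodendrocyte and neuronal lists had r = 0.39 (exact permutation p = 0.454, adjusted p = 0.730), rho = 0.31 (exact p = 0.564, adjusted p = 0.705) and r = -0.47 without the 2 farthest. The red blood cell and neuronal lists had r = -0.27 (exact permutation p = 0.532, adjusted p = 0.730), rho = -0.43 (exact p = 0.419, adjusted p = 0.699) and r = 0.50 without the 2 farthest. For the remaining 5 pairs r ranged from -0.49 for mir-124 with mir-9 to 0.31 for let-7 with the miR-17-92 list, with exact permutation p-values of at least 0.328, and rho ranged from -0.49 to 0.77 with exact p-values of at least 0.103.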

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

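Of 63 levels, shares and totals examined for a library far from the other 5, 4 stood apart by Dixon's criterion for 6 values. Chance flags about 1 in 20, or about 3.15 of 63. The 63 are not independent, since some rows, such as mir-9 and mir-29, entered both as scaled CPM and as share of a list.

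The mir-92 level was 21417 CPM in library 5, with an exact 95% interval of 21336 to 21498 CPM, against 15130 to 16897 CPM in the others. The predicted feature pred_185 was at 1.47 CPM in library 6, with an interval of 0.871 to 2.32 CPM, against 36.1 to 114.5 CPM in the others. The share of mir-9, which is the progenitor and neuron list, was 5.57% in library 6 with an interval of 5.55% to 5.58%, against 5.04% to 5.23%. As TMM-scaled CPM, mir-9 was not flagged, at 58086 CPM in library 6 against 48163 to 53692 CPM. The share of the miR-29 family was 0.154% in library 3 with an interval of 0.152% to 0.156%, against 0.198% to 0.219%. As TMM-scaled CPM, mir-29 was not flagged either, at 1467 CPM in library 3 against 1925 to 2287 CPM. Both flags thus passed the criterion only without the scaling. With it, library 6 was still highest for mir-9 and library 3 still lowest for mir-29.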

How the results depend on the processing

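The alternatives were fixed before the data were examined, except the trend without the called features and the lists with mir-8 and lin-4 matched. Without mir-181 in the total, the share of the 10 most abundant features was 72.9%. Because the total shrank, 32 of 43 named levels then moved by more than 1 SD. DESeq2 size factors and plain CPM moved none of the 44 named levels that far. Leaving out 1 of 6 libraries cannot move their mean by 1 SD, so it could not test the named levels. Requiring 1 or 100 counts in each library in place of 10 gave 245 or 131 features. The number of lists above the neuronal list rose from 1 to 5 with member medians and to 3 without mir-128. By medians the log2 ratio of the neuronal list reversed against mir-9 (-3.45), oligodendrocyte (-0.97), Hox-linked (-1.89) and let-7 (-4.21) families, and without mir-128 against mir-9 (-0.14) and let-7 (-0.89). The reversals without mir-128 follow from its share of the list. Those by medians set the middle of 9 neuronal rows against lists of 1 row (mir-9, let-7) or 2 rows (oligodendrocyte, Hox-linked). List length therefore enters them, as it enters the sums, and they do not compare summed contents. Leaving out any library gave 0 lists below and 0 above, since 5 libraries cannot give an exact sign-flip p under 0.0625; no direction changed. Matching mir-8 and lin-4 changed no count of lists, but moved the log2 ratio of the neuronal to the epithelium and skin list from 9.18 ± 1.11 to 7.38 ± 0.33 and narrowed that list's range between libraries from 6.83-fold to 1.97-fold. The log2 ratio of the neuronal list to the other ageing-linked families moved from -2.03 ± 0.22 to -2.19 ± 0.22.

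The count of 8 variable features was 3 as DESeq2 dispersion outliers (mir-375, mir-995 and pred_185, each among the 8), 177 by a Poisson index of dispersion, which allows for counting noise only, and 22 with the trend fitted without the features called, which include all 8. It was 8 with DESeq2 size factors, 10 without scaling, 10 and 6 with minimum means of 1 and 100 counts, and 6 to 9 when each library was left out. Without library 1 it was 9, of which 6 were among the 8. No pair passed the covariation test with plain CPM, DESeq2 size factors or a prior of 0.5; with 5 libraries the pairings are too few for a lone pair to pass after adjustment, so leaving out libraries says nothing here. Arm preference was not run because the counts name no arms. No paired analysis was possible because there is 1 group. Depth limits the rarest features: 2 to 8 counts lie behind the lowest values of mir-995, mir-883 and pred_347.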

Other observations

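The families singled out in these paragraphs were chosen after their values were seen, and so were all tests of explanations and of clusters in this part. Abundant families held a narrow range between libraries. Among 47 features with a mean of at least 1000 CPM, the median coefficient of variation was 13.1%, and it was 3.74% for mir-181, 3.87% for let-7, 4.87% for the retina and choroid plexus family mir-204 and 5.49% for mir-19. The widest was mir-135 at 62.4%, with 4915 and 4801 CPM in libraries 1 and 3 and 1190 to 2027 CPM in the others. It did not pass the edgeR variability test (adjusted p = 0.0791), but did without scaling beyond the total (0.0431), without library 6 (0.0298) and with the trend fitted without the called features (2.7e-05). Its adjusted p was 0.0927 to 0.394 without any 1 of the other libraries, highest without library 3. The tumour-associated family mir-221 ranged from 15261 CPM in library 1 to 37260 CPM in library 5. The fish families mir-724 and mir-458 stood at 18116 ± 2197 and 1513 ± 131 CPM (SD, n = 6).

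Several names belong to other kinds of organism. The 3 features with names of Epstein-Barr virus miRNAs took 0.480% ± 0.0312 of counts, almost all of it mir-BART15 at 4784 ± 222 CPM with a coefficient of variation of 4.64%. A set of 9 features with names of plant families, picked by hand and not a full list of such names, took 0.0503% ± 0.00708. The nematode name mir-228 stood at 1739 ± 176 CPM. How these names were assigned is not given in the sources used here.

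The correlations that follow belong to 1 family of 10, over which they were adjusted. Apart from the relations with mir-7, mir-8, mir-203 and mir-194, the lowest exact permutation p was 0.106. It was that of mir-205 with mir-133 of the muscle list (r = 0.72, adjusted p = 0.3, and r = 0.91 without the 2 farthest libraries). Their rho was 0.77 (exact p = 0.103). With 1 group, the design names no biological contrast to set against the explanations weighed. The first pattern is mir-375. Depth or scaling would move every feature alike, but between libraries 2 and 6 the raw count of mir-375 differed 362.1-fold and those of the 213 other tested features by a median of 1.21-fold (5th to 95th percentile 0.581 to 2.63), which argues against it. The neuronal share differed by only 1.48-fold, which argues against a library of another tissue. Uneven inclusion of pituitary or other endocrine tissue may explain it, but no relation of mir-7 with mir-375 was found (r = 0.0202, exact permutation p = 0.954, adjusted p = 0.954; rho = -0.26, exact p = 0.658; r = -0.20 without the 2 farthest libraries), and the relation with mir-8 did not pass (r = 0.46, exact p = 0.318, adjusted p = 0.398; rho = 0.26, exact p = 0.658; r = 0.73 without the 2 farthest). As mir-7 is also made in brain, its baseline could hide a small share of such tissue, so this stays open, as does a difference between animals.

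The second pattern is in mir-205 and mir-203, neither of which passed the edgeR variability test over all features (adjusted p = 0.0872 and 0.9999; 0.9999 for mir-205 without library 3). As fixed, the epithelium and skin list was highest in library 3 at 0.0567% and lowest in library 6 at 0.00830%, whereas with mir-8 added it was highest in library 4 at 0.0867% and lowest in library 1 at 0.0440%. Between libraries 3 and 6 the raw count of mir-205 differed 10.2-fold and the other 213 tested features by a median of 1.44-fold (5th to 95th percentile 0.646 to 2.86), which argues against depth or scaling. Carried-over skin or other epithelium would raise mir-203 with mir-205, and they had r = 0.94 (exact permutation p = 0.00694, adjusted p = 0.0347) and rho = 0.94 (exact p = 0.0167), though r was 0.68 without the 2 farthest libraries. It would also raise mir-8, which had a negative relation with mir-205 that did not pass (r = -0.71, exact p = 0.129, adjusted p = 0.3; rho = -0.71, exact p = 0.136; r = -0.41 without the 2 farthest). Carried-over epithelium may be hidden by other sources of mir-8 and stays open, as does a difference between animals.

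The third pattern is mir-192, whose raw count differed 15.9-fold between libraries 1 and 6 while the other 213 tested features differed by a median ratio of 0.980 (5th to 95th percentile 0.494 to 1.84), which argues against depth or scaling. Its neighbour in a vertebrate genomic cluster, mir-194, ranked the 6 libraries in the same order (rho = 1, exact permutation p = 0.00278) with r = 0.91 (exact p = 0.00139, adjusted p = 0.0139) and r = 0.84 without the 2 farthest libraries. The sizes differed, however: mir-194 ranged 2.60-fold and did not pass the edgeR variability test (adjusted p = 0.9999), against 15.8-fold for mir-192. A change shared by the cluster could account for part of the spread at most unless mir-194 has another source, so it stays open. Carried-over gut, liver or kidney tissue was not tested as such; liver mir-122 ranged only from 9.10 to 11.3 CPM.

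A hypothesis drawn from this was that families sharing a genomic cluster vary together between libraries. Of 15 pairs known as clustered in vertebrates, 5 were left out because their r was known when the hypothesis was drawn, mir-192 with mir-194 among them; they were left out only after the median over all 15 (0.63) had been seen. Over the other 10 pairs of 18 families the median r was 0.597 and r was above 0 for 8 pairs. That median exceeded 99.76% of 10000 random relabellings of the same families, whose median was 0.08. It was 0.67 without mir-15 with mir-16 and mir-130 with mir-301, whose sequences are alike and could share reads. Leaving out each library gave medians of 0.47 to 0.75, and the median then exceeded only 93.79% of relabellings without library 4 and 94.1% without library 5, so the excess over chance depends in part on single libraries. Among these pairs mir-23 with mir-27 reached 0.89 and mir-216 with mir-217 reached 0.82, whereas mir-17 with mir-19 (-0.02) and mir-193 with mir-365 (-0.44) did not follow. Positions in the killifish genome were not used here, and 6 libraries cannot separate shared transcription from shared tissue.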
